A study of Homo sapiens with 8 samples.

How the data were processed

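The deposited data comprise 8 Agilent single-colour arrays of PANC-1 cells, 4 with a control hairpin (shControl) and 4 with a hairpin against TRIP12 (shTRIP12). Per the labels' protocols, cells were grown in DMEM with 1 g/L glucose and 10% serum, and Cy3-labelled cRNA was made from 200 ng of total RNA. Each deposited scanner file gives spot intensity values, which the authors obtained with Agilent Feature Extraction 10.10.1.1 per the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and detrended within the array, with low values replaced by surrogates, and was not scaled between arrays. The notes also name limma, for which no version is given in the sources used here. The deposited value table of the series holds log2 values for 28273 probes per array. Set against the scanner files, these log2 values matched the log2 median spot signal of the same array at r of 0.999 or above, with array medians of 8.06 on all 8 arrays, so the scale is log2 and the genes were not centred. The background step behind them is not given in the sources used here.

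Of 62976 spots per array, 58717 are not controls and represent 50599 probes. The log2 processed intensity minus the 75th percentile of the non-control spots of the array was used, spots with an outlier flag were left out, and spots of 1 probe were averaged. The 75th percentile of the processed signal was 533, 662, 359 and 452 for shControl 1 to 4 and 723, 548, 541 and 471 for shTRIP12 1 to 4. A probe entered the tests when it was well above background on all 4 arrays of at least 1 group, which left 27886 probes. A gene was represented by its brightest passing probe; 4989 of the 21023 genes had several, and TRIP12 is among the genes whose probes disagree in direction. Probes were named through a reference gene table of assembly GRCh38.p14, 28174 by accession, 2618 by symbol and 620 by synonym, while 19187 kept the name in the files. Of the genes tested, 15554 had a reference symbol and 13967 were protein-coding. Coordinates are those of the array files, in hg19; no genome sequence was used here. The number of arrays limits the precision of every value.

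The groups were compared with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8) by lmFit and eBayes on group alone, with two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. Sets were tested with limma's camera at a preset correlation of 0.01 over 36 gene lists with at least 5 tested members, adjusted over the lists, and again with an estimated correlation, on ranks and with fry. The direction of a list is that of the median of its members, a choice made after a first look at the results in place of the direction given by camera. The lists were for mitosis, spindle checkpoint, cohesin and condensin, DNA replication, homologous recombination, histones, p53 targets, TRIP12 substrates, HECT ligases, proteasome, SWI/SNF, mesenchymal, epithelial, extracellular matrix, TGF-beta, YAP/TEAD, interferon, NF-kappaB, MAPK, unfolded protein response, heat shock, NRF2, cholesterol, hypoxia, oxidative phosphorylation, ribosomal protein, ribosome biogenesis, autophagy, Notch and Wnt, and adhesion genes, and for acinar, ductal, endocrine, fibroblast, immune and endothelial markers. Chromosomes were tested as sets with camera. The SD of the running median over 41 neighbouring genes was set against 1000 random gene orders.

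Genes were named by a rule fixed before the data were examined: TRIP12 first, then up to 12 rises and 12 falls past the adjusted p of 0.05 with non-overlapping groups, a reference symbol and signal well above background on at least 2 arrays of each group, then up to 3 genes per direction well above background in 1 group only, then the members of each list with the lowest p, 4 for a called list and 2 for another. The design, the lists and 27 alternative settings were also fixed then: another background correction, other normalizations, other filters and probe choices, slide or replicate number as a block, other variance models, the authors' deposited log2 values, and leaving out each array. The fits without shControl 3 and 4, those within each slide and the test of an interaction of group and slide were added after the data were seen. Where a group was not well above background on any array, the fold was bounded by setting the mean of the bright group against, per array of the dim group, the higher of the dimmest signal well above background and the probe's own signal. With all 35 splits of the 8 arrays into 4 and 4, the count of genes and lists was repeated.

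The procedure was tested on simulated data with 200 changed genes among 21023 for the comparison of shTRIP12 with shControl. At the spread of the 8-array fit it recovered 1 of 50 genes changed by 1 log2 unit, 35 of 50 changed by 2, 49 of 50 changed by 4 and 48 of 50 changed by 6, with 11 false calls. At the spread within group and slide it recovered 19, 40, 47 and 49 of 50, with 12 false calls. In simulated lists of 40 independent genes, the 1 shifted list was called and 0 of 35 others were. In the real lists the estimated correlation between members reached 0.82, for mitosis. The simulation therefore does not show how often such lists are called falsely.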

Results

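Gene expression was profiled in PANC-1 cells, an established line derived from a human pancreatic carcinoma, that carried either a short hairpin RNA against TRIP12 (shTRIP12) or a control hairpin (shControl). TRIP12 encodes a ubiquitin ligase of the HECT family, an enzyme class that attaches ubiquitin to target proteins. Each group held 4 samples that the labels give as biological replicates, harvested untreated during exponential growth. Each sample was hybridised alone to 1 single-colour Agilent array with 62976 spots. Between 58.8% and 64.5% of probes lay well above background on an array, and 0 spots were saturated on any array. The arrays lay on 2 slides, with replicates 1 and 2 of both groups on slide 1 and replicates 3 and 4 on slide 2, so each slide held 2 arrays of each group. All shControl arrays lay in array column 1 of a slide and all shTRIP12 arrays in column 2, so position on the slide and group cannot be told apart. Levels are given as log2 signal relative to the 75th percentile of the array, and a log2 fold change is shTRIP12 minus shControl.

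TRIP12, the target of the hairpin, was read first. The probe for its mRNA (chromosome 2, 230631938 to 230631997, hg19) had a level of 3.30 ± 0.55 (SD, n = 4) in shControl and 0.89 ± 0.39 (SD, n = 4) in shTRIP12, which is 18.8% of the control level. It was lower on all 4 shTRIP12 arrays (0.90, 0.63, 1.44 and 0.61 for replicates 1 to 4) than on any shControl array (3.80, 3.74, 2.98 and 2.69). The log2 fold change was -2.41 (SE 0.33), and a two-sided exact permutation test gave p = 0.0286, the smallest that the 70 assignments of 8 arrays allow. In limma over all genes the adjusted p was 0.0644, which missed the threshold of 0.05, and with slide as a block it was 0.0232 for the same fold change. The block assumes the same slide shift in both groups, which did not hold in 1192 genes (interaction of group and slide, limma adjusted p under 0.05). Leaving out shControl 2 brought it past the threshold (limma adjusted p = 0.0386), and without shControl 3 and 4 the log2 fold change was -2.88 (SE 0.30, limma adjusted p = 0.116, 13.6% of control). Within slide 1 the log2 fold change was -3.01 (limma adjusted p = 0.136, 12.4% of control) and within slide 2 it was -1.81 (limma adjusted p = 0.0377, 28.5% of control). A second TRIP12 probe, in an intron that some transcripts retain (chromosome 2, 230695793 to 230695852), was higher in shTRIP12, at -1.98 ± 0.23 (SD, n = 4) against -3.28 ± 0.45 (SD, n = 4). It had a log2 fold change of 1.30 (SE 0.27) and a limma adjusted p over all probes of 0.0936. With the mean of both probes the TRIP12 log2 fold change was -0.55 (limma adjusted p = 0.307).

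**Figure D1:**
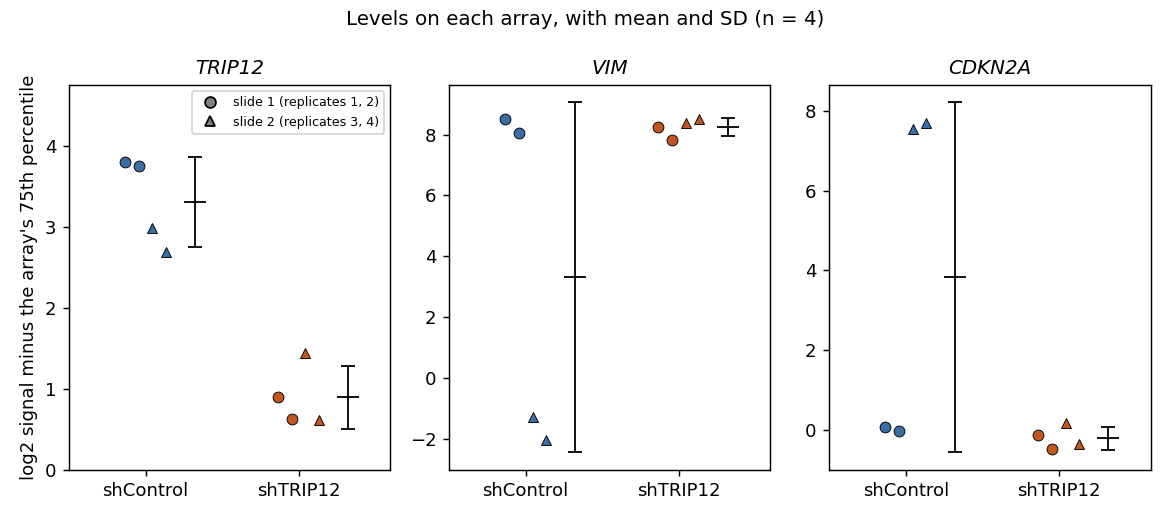
Level of TRIP12, VIM and CDKN2A on each array, as log2 signal minus the 75th percentile of the array, for shControl and shTRIP12; circles are slide 1, triangles slide 2, and bars show the mean and SD of 4 arrays. TRIP12 was lower on every shTRIP12 array (mean 0.89 against 3.30), while VIM and CDKN2A on shControl 3 and 4 lay far from their levels on the other 6 arrays.

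The control arrays shControl 3 and 4 stood apart from the other 6 arrays. VIM, which encodes the intermediate filament vimentin, had a mean level of 8.27 on shControl 1 and 2, -1.65 on shControl 3 and 4, which is 972-fold lower, and 8.24 ± 0.29 (SD, n = 4) in shTRIP12. CDKN2A, the gene of the cell cycle inhibitor p16, was 191-fold higher on shControl 3 and 4 (mean 7.62) than on shControl 1 and 2 (mean 0.04), and lay at -0.19 ± 0.29 (SD, n = 4) in shTRIP12. The epithelial genes KRT7 and EPCAM had means of 9.65 and 6.58 on shControl 3 and 4 against 3.64 and 2.20 on shControl 1 and 2, and the cytokine genes IL6 and INHBA had means of 5.72 and 7.50 against -5.01 and -3.10. These 6 genes were picked after their values were seen. Across genes, which are not independent replicates, shControl 3 and 4 correlated with each other at r = 0.978 and with the other arrays at 0.841 to 0.887, whereas the other 6 arrays correlated at 0.932 to 0.974 among themselves. Of 21023 genes, 871 were at least 8-fold lower and 271 at least 8-fold higher on shControl 3 and 4 than on shControl 1 and 2, against 68 and 69 genes between the same slides in shTRIP12. Counts of calls and list medians are therefore given with all 8 arrays, as fixed before the data were examined. Beside them stand values without shControl 3 and 4, an alternative chosen after seeing the data. Counts of members adjusted over a list alone are given without these arrays where they differ. That fit sets the controls of slide 1 against shTRIP12 arrays of both slides with no slide term, so it partly mixes slide with group. For a named member of a list the second value follows where leaving out these arrays changed its log2 fold change by a factor above 1.5. It is also given for some members that changed by less, such as EREG, DUSP5, IER3 and CDH1, so brackets alone do not mark such a change. This factor compares log2 values, so a member without brackets can still have moved by more than 1.5-fold in signal.

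**Figure D2:**
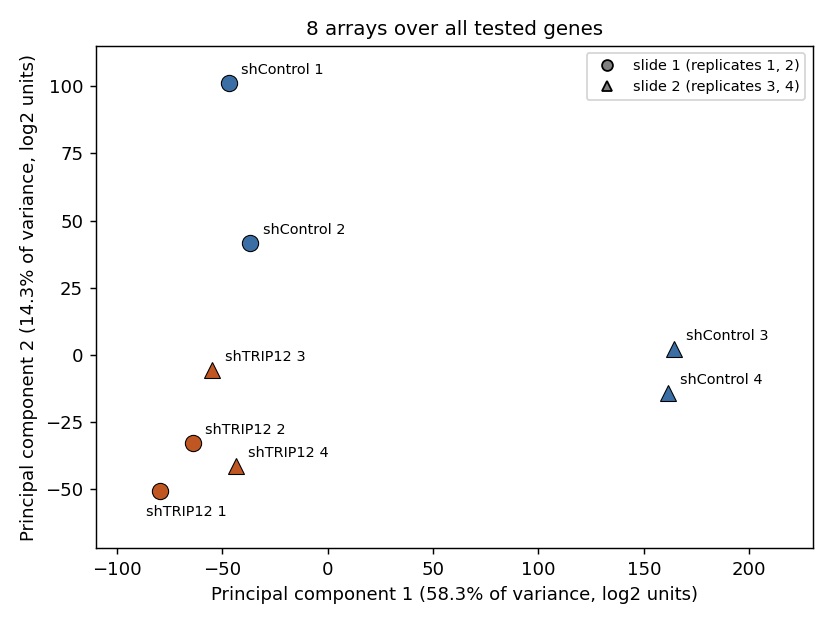
The 8 arrays on the first and second principal components of all tested genes (58.3% and 14.3% of the variance, log2 units); blue is shControl, orange is shTRIP12, circles are slide 1 and triangles slide 2. shControl 3 and 4 lie apart from the other 6 arrays along the first component.

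Knockdown of TRIP12 was compared with the control hairpin to find which transcripts differ when TRIP12 is reduced. With all 8 arrays, 18 of 21023 genes passed an adjusted p of 0.05 in limma, 9 higher and 9 lower in shTRIP12. Among those that rose were GBP2, an interferon-induced guanylate-binding protein (log2 fold change 5.43, SE 0.65, adjusted p = 0.0468), CDH18, a cadherin (5.11, SE 0.50, adjusted p = 0.0303), and PAG1, a membrane adaptor of Src family kinases (3.29, SE 0.30, adjusted p = 0.0290). TULP3, a protein of ciliary trafficking, rose by a log2 fold change of 1.95 (SE 0.25, adjusted p = 0.0489) and MGAT4B, an N-glycan branching enzyme, by 1.85 (SE 0.24, adjusted p = 0.0489). Genes that fell included the homeobox genes MNX1 (-2.63, SE 0.32, adjusted p = 0.0468) and SIX4 (-2.20, SE 0.28, adjusted p = 0.0483), ACLY, the enzyme that makes cytosolic acetyl-CoA from citrate (-1.80, SE 0.20, adjusted p = 0.0337), and LRP8, a lipoprotein receptor (-1.59, SE 0.20, adjusted p = 0.0483).

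CLPSL2 (-3.44, SE 0.45, adjusted p = 0.0489), the xylosyl kinase gene FAM20B (-1.66, SE 0.19, adjusted p = 0.0468) and DCAF7 (-1.65, SE 0.20, adjusted p = 0.0468) also fell. KLRC3, a lectin-like receptor of natural killer cells, was well above background on all 4 shTRIP12 arrays and on 0 of 4 shControl arrays, and was at least 2.23-fold higher in shTRIP12 (adjusted p = 0.0290). LRMDA, a gene of melanocyte differentiation, was well above background on all 4 shControl arrays and on 0 of 4 shTRIP12 arrays, and was at least 14.2-fold lower (adjusted p = 0.0468). These bounds set the mean of the bright group against, for each array of the dim group, the higher of the array's dimmest signal well above background and the probe's own signal. They hold for the main processing only. Across 18 planned settings the KLRC3 log2 fold change lay between 0.20 and 2.95, and 9 kept the call. For LRMDA it lay between -5.35 and -1.66 across 19 settings, and 8 kept the call. GBP2 and PAG1 were well above background on 2 of 4 shControl arrays and CDH18 on 3 of 4, so their fold changes rest partly on dim signals. The other 4 genes past the threshold have no symbol in the reference table and were named after their values were seen. A_33_P3279505 was at least 3.90-fold, XLOC_l2_000706 at least 1.91-fold and XLOC_007189 2.82 log2 units higher, and LOC100505577 was at least 3.29-fold lower. At their smallest in planned settings the log2 fold changes of these genes were 0.48, 0.21, 0.79 and -0.72 in that order. Their calls were kept in 6 of 19, 6 of 18, 8 of 19 and 8 of 19 settings.

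At the probes of these genes, GBP2 lies on chromosome 1 (89575896 to 89578160, hg19), CDH18 on chromosome 5 (19473172 to 19473231), ACLY on chromosome 17 (40023968 to 40024027) and MNX1 on chromosome 7 (156797655 to 156797714). Mean levels in shControl and shTRIP12 were 2.75 ± 0.19 and 0.95 ± 0.14 for ACLY, -0.30 ± 0.20 and -2.94 ± 0.62 for MNX1, -4.53 ± 1.01 and 0.57 ± 0.46 for CDH18, and -5.04 ± 1.28 and 0.39 ± 0.80 for GBP2 (SD, n = 4 each). Without shControl 3 and 4 the log2 fold changes were, for example, 4.57 for GBP2, 4.47 for CDH18, 2.91 for PAG1, -2.47 for MNX1 and -1.76 for ACLY. All 18 genes kept their direction, which was fixed in advance for those named by the rule, since their groups do not overlap.

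All 18 genes had an absolute log2 fold change of at least 1, and 4080 genes had an unadjusted p under 0.05. Without shControl 3 and 4, limma called 0 genes (2827 at an unadjusted p under 0.05), and the adjusted p of the 18 genes lay between 0.111 and 0.172. With slide as a block, limma called 1064 genes (443 higher, 621 lower) and all 18 passed. Such a block assumes the same slide shift in both groups. Over genes at least 8-fold apart between slides in shControl, shTRIP12 carried 0.0237 of that shift (slope through 0). The assumption does not hold for those genes, so counts with this block carry that limit. Within slide 1 it called 0 genes (3169 at an unadjusted p under 0.05), and within slide 2, where the control arrays are shControl 3 and 4, it called 3632 (2119 higher, 1513 lower), all 18 among them. The count was 42 without shControl 1, 277 without shControl 2, 2 without shControl 3 and 0 without shControl 4 (2943 at an unadjusted p under 0.05), and it was 0 when any 1 shTRIP12 array was left out (2883 to 3606 at an unadjusted p under 0.05). Without a filter on dim probes limma called 0 genes (4807 at an unadjusted p under 0.05), with probes well above background on all 8 arrays 0 (3610), and with array weights 3940. The weights did not bring values closer to the fit without shControl 3 and 4. The TRIP12 log2 fold change was -2.41 unweighted, -2.05 weighted and -2.88 without those arrays. The NF-kappaB list median was 0.44, -0.31 and 1.40 in the same order. Another background correction gave 27 higher and 20 lower, quantile normalization of the processed signals 4 higher and 7 lower, median scaling 3 higher and 8 lower, and quantile normalization of median signals 16 higher and 10 lower. The 4 values of the groups did not overlap in 2436 genes (1141 higher, 1295 lower), 11.6% of genes. Averaged over all groupings of the 8 arrays into 4 and 4, the share is 2.86%. A single grouping can lie far from this average, and the share was not computed for the other splits, so no excess is claimed.

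**Figure D3:**
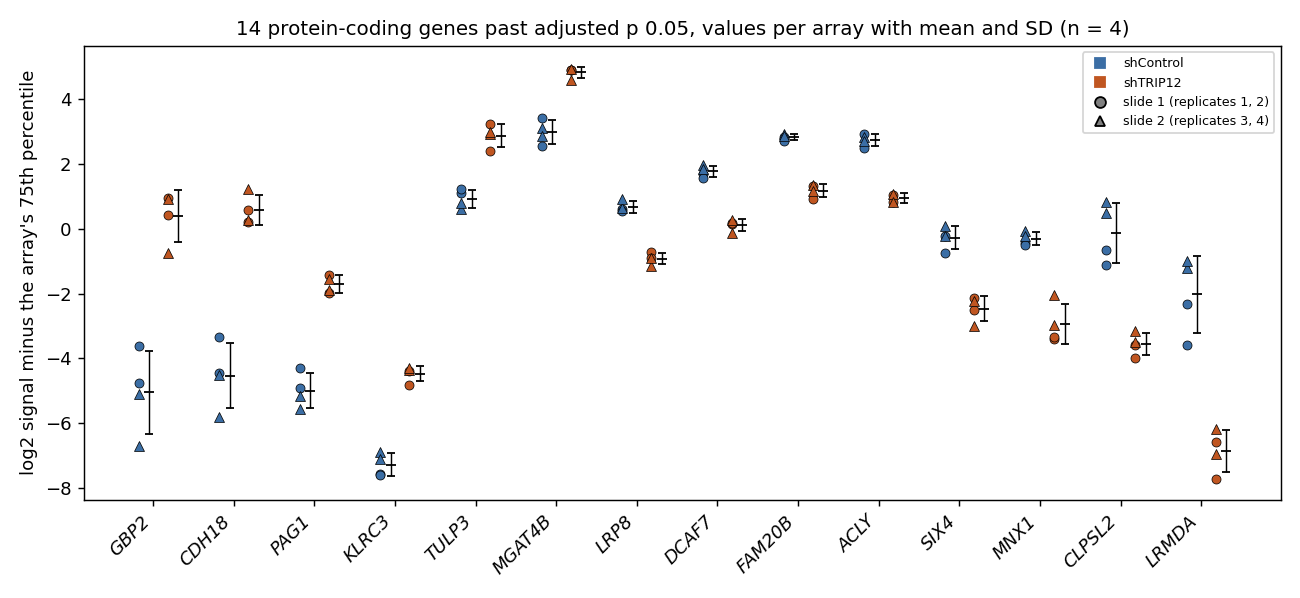
Levels of the 14 protein-coding genes past an adjusted p of 0.05 on each array, as log2 signal minus the 75th percentile of the array; blue is shControl, orange is shTRIP12, circles are slide 1, triangles slide 2, and bars show the mean and SD of 4 arrays. The groups do not overlap in any of the 14 genes; KLRC3 in shControl and LRMDA in shTRIP12 were not well above background.

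The groups were then compared over 36 gene lists fixed before the data were examined. Camera with a preset correlation of 0.01 between members placed 18 lists past an adjusted p of 0.05, 7 higher and 11 lower in shTRIP12. The same test called 2 to 18 lists for the other splits of the 8 arrays into 4 and 4, so its p values do not measure chance here. With a correlation estimated per list, camera called 0 of the 36 lists (3 at an unadjusted p under 0.05), with a lowest adjusted p of 0.288, and fry, which does not compare a list with other genes, called 0 (16 at an unadjusted p under 0.05, lowest adjusted p = 0.0615). Of the 18 lists, 14 were also called without shControl 3 and 4, 17 with slide as a block, 15 within slide 1 and 13 within slide 2. These recounts all use the preset correlation. With an estimated correlation and without shControl 3 and 4, no list was called by camera (lowest adjusted p = 0.475). The epithelial, MAPK and adhesion lists were lost within slide 1 (adjusted p = 0.827, 0.530 and 0.122), and the cohesin, TGF-beta, stress response, cholesterol and autophagy lists within slide 2 (0.169, 0.270, 0.809, 0.313 and 0.209). Of 1107 genes in any list, GBP2 alone passed over all genes in limma, and 372 had an unadjusted p under 0.05. The members named below for each list are therefore given with their values.

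With all 8 arrays, genes of mitosis had the lowest median of the 36 lists. Of 38 members tested, 37 were lower in shTRIP12, with a median log2 fold change of -1.54 over all 8 arrays, -1.39 without shControl 3 and 4, -1.98 within slide 1 and -1.14 within slide 2 (camera adjusted p = 2.31e-16 with the preset correlation, 1.01e-15 with slide as a block). This call was lost with an estimated correlation (adjusted p = 0.417 with an estimated correlation). Adjusted over the list alone, 35 members fell and 1 rose. Without shControl 3 and 4, 37 members were still lower, but 0 passed adjusted over the list alone. Over all genes 0 passed in limma with all 8 arrays, and 36 had an unadjusted p under 0.05. The kinase AURKA differed by -1.97 log2 units (SE 0.39), CDC20, an activator of the anaphase-promoting complex, by -2.15 (SE 0.46) and ECT2, a regulator of cytokinesis, by -1.45 (SE 0.30), while the phosphatase gene CDC25B differed by 1.80 (SE 0.34). The spindle checkpoint and kinetochore list had a median of -1.32 (-0.95 without shControl 3 and 4, -1.40 and -1.17 within slides 1 and 2) over 40 members (adjusted p = 1.25e-13, adjusted p = 0.417 with an estimated correlation). In all 28 members fell, adjusted over the list alone, but 0 without shControl 3 and 4. With all 8 arrays 0 passed over all genes in limma (31 at an unadjusted p under 0.05). Examples were NDC80 (-2.03), NUF2 (-1.78), DSN1 (-1.65) and MIS12 (-1.37), all of the outer kinetochore. The mean of the mitosis list was 2.38, 2.37, 3.13 and 2.39 on shControl 1 to 4 and 0.34, 0.59, 2.26 and 0.98 on shTRIP12 1 to 4, so shTRIP12 3 lay close to the control arrays.

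DNA replication and G1/S genes had a median of -1.28 (-0.76 without shControl 3 and 4, -1.11 within slide 1, -1.48 within slide 2) over 50 members (adjusted p = 5.28e-14 with the preset correlation, adjusted p = 0.417 with an estimated correlation). Among its members 29 fell and 1 rose, adjusted over the list alone, against 0 over all genes in limma (38 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 0 passed adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, differed by -2.64 (SE 0.47), the helicase subunit MCM5 by -1.57 (SE 0.36), the clamp loader subunit RFC4 by -1.27 (-0.82 without shControl 3 and 4) and the transcription factor E2F1 by -1.91 (-1.16). Replication-dependent histone genes had a median of -1.28 over 49 members (-1.04 without shControl 3 and 4, -1.52 and -1.15 within the slides; adjusted p = 2.66e-07, adjusted p = 0.440 with an estimated correlation). In limma 0 histone genes passed adjusted over the list alone and 31 had an unadjusted p under 0.05. The 4 histone genes named by the rule were H4C13 (-1.69), H4C3 (-1.66), H2BC21 (-1.28) and H2AC17 (-1.17).

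Homologous recombination genes had a median of -0.73 over 43 members (-0.40 without shControl 3 and 4, -0.54 and -0.88 within the slides; adjusted p = 1.57e-05, adjusted p = 0.417 with an estimated correlation). In limma 0 of them passed, adjusted over the list alone, and 15 had an unadjusted p under 0.05. The recombinase paralogue RAD51C stood at -1.82 (-0.95 without shControl 3 and 4), the nuclease EXO1 at -1.94 (-1.16), PARP2 at -0.82 (-0.50) and the helicase BLM at -1.31. Cohesin and condensin genes, which hold and compact chromosomes, had a median of -0.60 over 21 members (-0.46 without shControl 3 and 4, -0.58 and -0.60 within the slides; adjusted p = 0.00250, adjusted p = 0.440 with an estimated correlation). Of its members 7 fell, adjusted over the list alone, and 0 passed over all genes in limma (11 at an unadjusted p under 0.05). The condensin subunit SMC4 stood at -1.36 (-0.89 without shControl 3 and 4), NCAPD3 at -1.08 (-0.71), NCAPG at -1.88 and the cohesin protector CDCA5 at -1.41.

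Interferon-stimulated genes were higher in shTRIP12. Of 47 members tested, 43 were higher, with a median log2 fold change of 0.87 over all 8 arrays, 0.79 without shControl 3 and 4, 0.90 within slide 1 and 1.01 within slide 2 (camera adjusted p = 3.61e-10 with the preset correlation, 1.87e-09 with slide as a block). The call was lost with an estimated correlation (adjusted p = 0.288 with an estimated correlation). Of these genes 6 rose, adjusted over the list alone, against 1, GBP2, over all genes in limma and 19 at an unadjusted p under 0.05. Leaving out shControl 3 and 4, 4 rose adjusted over the list alone. TRIM22, an antiviral tripartite motif protein, was well above background on 0 of 4 shControl arrays and at least 7.94-fold higher in shTRIP12 (limma adjusted p = 0.0682). SAMD9L differed by 3.65 log2 units (SE 0.83, 4.95 without shControl 3 and 4) and the helicase gene DDX60 by 1.41 (SE 0.34, 1.45 without these arrays). The mean of the list was 0.70 on shTRIP12 3 against 1.24 to 1.32 on the other shTRIP12 arrays.

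Mesenchymal and epithelial-mesenchymal transition genes had a median of 1.08 over 29 members, 22 of them higher in shTRIP12 (0.98 without shControl 3 and 4, 0.61 and 0.59 within the slides; adjusted p = 0.00186, adjusted p = 0.288 with an estimated correlation). In this list 3 members rose and 1 fell, adjusted over the list alone, and 0 passed over all genes in limma (10 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 3 rose and 2 fell adjusted over the list alone. The matrix protein gene TNC differed by 4.70 (SE 0.77) and WNT5A by 3.59 (SE 0.76), well above background on 3 and 1 of 4 shControl arrays, ITGB1 by 1.32 (SE 0.29), and the smooth muscle actin gene ACTA2 by -2.64 (SE 0.57). Without shControl 3 and 4 these values were 5.63, 2.76, 1.03 and -2.84 in that order. Without shControl 1 the median of the list was 0.65. VIM, also in the list, had a log2 fold change of 4.93 with all 8 arrays and -0.03 without shControl 3 and 4. Epithelial junction genes had a median of -0.61 over 33 members (-0.33 without shControl 3 and 4, -0.21 within slide 1 and -1.59 within slide 2; adjusted p = 0.0427, adjusted p = 0.562 with an estimated correlation). This call was lost without shControl 3 and 4 (adjusted p = 0.575). It was also lost without shControl 3 (median -0.27, adjusted p = 0.0559), shControl 4 (-0.43, adjusted p = 0.0775), shTRIP12 1 (-0.54, adjusted p = 0.0806), shTRIP12 3 (-0.62, adjusted p = 0.0804) or shTRIP12 4 (-0.36, adjusted p = 0.0706). Without shControl 1 the median was -0.93 and the call was kept. Of 24 planned settings, 9 kept the epithelial call. Here 8 members fell and 1 rose, adjusted over the list alone, and 0 passed over all genes in limma (12 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 0 fell and 1 rose adjusted over the list alone. CDH1, the gene of E-cadherin, differed by -3.39 (SE 0.68, -2.57 without shControl 3 and 4) and GRHL1 by -1.77, while the claudin gene CLDN4 differed by 2.82 (SE 0.46, 2.05 without shControl 3 and 4).

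Adhesion and integrin genes had a median of 0.57 over 31 members (0.29 without shControl 3 and 4, 0.20 and 0.71 within the slides; adjusted p = 0.00134, adjusted p = 0.417 with an estimated correlation), and 4 members rose adjusted over the list alone (9 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 1 rose and 1 fell adjusted over the list alone. The integrin genes ITGA3 and ITGB8 differed by 1.93 and 4.08, the latter well above background on 2 of 4 shControl arrays, and FERMT2 by 1.21 (0.73 without shControl 3 and 4). TGF-beta target genes had a median of 1.08 over 23 members (0.36 without shControl 3 and 4, 0.83 and 0.43 within the slides; adjusted p = 0.0342, adjusted p = 0.417 with an estimated correlation). In limma 0 members passed adjusted over the list alone (2 rose without shControl 3 and 4), and 5 had an unadjusted p under 0.05. ID2 differed by 4.83 (2.19 without shControl 3 and 4), ID3 by 2.51 (1.27), LTBP3 by 1.80 (0.71) and SKI by 1.09, so the values of 3 of these 4 genes rest in large part on shControl 3 and 4. MAPK feedback and immediate early genes had a median of 0.60 over 36 members, but 0.10 without shControl 3 and 4 and -0.14 within slide 1 against 0.88 within slide 2 (adjusted p = 0.0144, adjusted p = 0.440 with an estimated correlation). The ligand gene EREG differed by 5.20 (3.65 without shControl 3 and 4), the phosphatase gene DUSP5 by 2.30 (1.95), IER3 by 1.47 (2.13) and ETV4 by -1.87 (-1.28). In this list 2 members rose and 1 fell, adjusted over the list alone, and 0 passed over all genes in limma (6 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 3 rose and 1 fell adjusted over the list alone. The adhesion, TGF-beta and MAPK calls were lost without shControl 3 and 4, with adjusted p of 0.0747, 0.0747 and 0.749. The TGF-beta call was also lost without shControl 1 (median 0.60, adjusted p = 0.0620), shControl 4 (0.77, adjusted p = 0.0689), shTRIP12 1 (1.13, adjusted p = 0.0806) or shTRIP12 2 (0.38, adjusted p = 0.150). The MAPK call was lost without shControl 4 (median 0.20, adjusted p = 0.0959) or shTRIP12 4 (0.40, adjusted p = 0.0633).

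Cholesterol synthesis genes had a median of -0.78 over 24 members and -1.14 without shControl 3 and 4, with -1.30 within slide 1 and -0.31 within slide 2 (adjusted p = 6.89e-06, adjusted p = 0.417 with an estimated correlation). Of its members 7 fell, adjusted over the list alone, against 0 over all genes in limma and 11 at an unadjusted p under 0.05. Leaving out shControl 3 and 4, 15 fell adjusted over the list alone. The prenyl synthase gene FDPS stood at -1.98 (SE 0.33), IDI1 at -1.77 (SE 0.33), EBP at -1.54 (SE 0.28) and FDFT1, squalene synthase, at -1.44 (SE 0.36). Oxidative phosphorylation genes had a median of -0.51 over 72 members, 65 of them lower (-0.47 without shControl 3 and 4, -0.61 and -0.35 within the slides; adjusted p = 1.44e-09, adjusted p = 0.417 with an estimated correlation). The ATP synthase genes ATP5MC1 (-1.61), ATP5F1D (-1.13) and ATP5F1C (-1.02) and the complex I gene NDUFC2 (-0.67) were named, and 0 members passed adjusted over the list alone in limma (33 at an unadjusted p under 0.05). Proteasome subunit genes had a median of -0.52 over 40 members, 37 of them lower (-0.32 without shControl 3 and 4, -0.59 and -0.63 within the slides; adjusted p = 2.21e-06, adjusted p = 0.440 with an estimated correlation). Its named members were PSMB3 (-1.02), PSMC3 (-0.96), PSMC5 (-0.89) and PSMA3 (-0.72). In limma 0 members passed adjusted over the list alone and 13 had an unadjusted p under 0.05.

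Ribosome biogenesis genes had a median of -0.57 over 46 members (-0.25 without shControl 3 and 4, -0.51 and -0.54 within the slides; adjusted p = 1.53e-06, adjusted p = 0.440 with an estimated correlation), and 2 fell adjusted over the list alone (14 at an unadjusted p under 0.05). Leaving out shControl 3 and 4, 0 passed adjusted over the list alone. The nucleolar factor TSR1 stood at -1.53 (-0.99 without shControl 3 and 4), MYBBP1A at -1.60 (-0.73), DDX56 at -1.03 (-0.63) and UTP18 at -0.92. Autophagy and lysosome genes had a median of 0.24 over 43 members (0.33 without shControl 3 and 4, 0.28 and 0.18 within the slides; adjusted p = 0.00942, adjusted p = 0.417 with an estimated correlation). Of its members 2 rose, adjusted over the list alone (11 at an unadjusted p under 0.05), but 0 without shControl 3 and 4. The median of the list was 0.45 without shTRIP12 3. The lysosomal protease genes CTSD and CTSB differed by 2.63 (SE 0.59, 1.68 without shControl 3 and 4) and 2.08 (SE 0.59). Genes of the unfolded protein response and amino acid stress had a median of 0.40 over 42 members (0.44 without shControl 3 and 4, 0.61 and 0.05 within the slides; adjusted p = 0.0409, adjusted p = 0.804 with an estimated correlation). With slide as a block this was the only called list that missed the threshold (adjusted p = 0.0600). The call was also lost without shControl 1 (median 0.077, adjusted p = 0.685), shControl 3 (0.12, adjusted p = 0.656), shTRIP12 1 (0.40, adjusted p = 0.0914), shTRIP12 2 (0.44, adjusted p = 0.141) or shTRIP12 4 (0.30, adjusted p = 0.119). Of 24 planned settings, 13 kept this call. The median was 0.62 without shControl 2 and 0.68 without shControl 4, so its size rests on single shControl arrays. In limma 0 of its members passed adjusted over the list alone (1 rose without shControl 3 and 4), and 1 had an unadjusted p under 0.05. The secreted hormone gene STC2 differed by 2.78 and VEGFA by 1.34. HSPA5 differed by 1.54 and ATF5 by 1.19, but by 0.88 and 0.18 without shControl 3 and 4, so these values rest in part on those arrays.

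**Figure D4:**
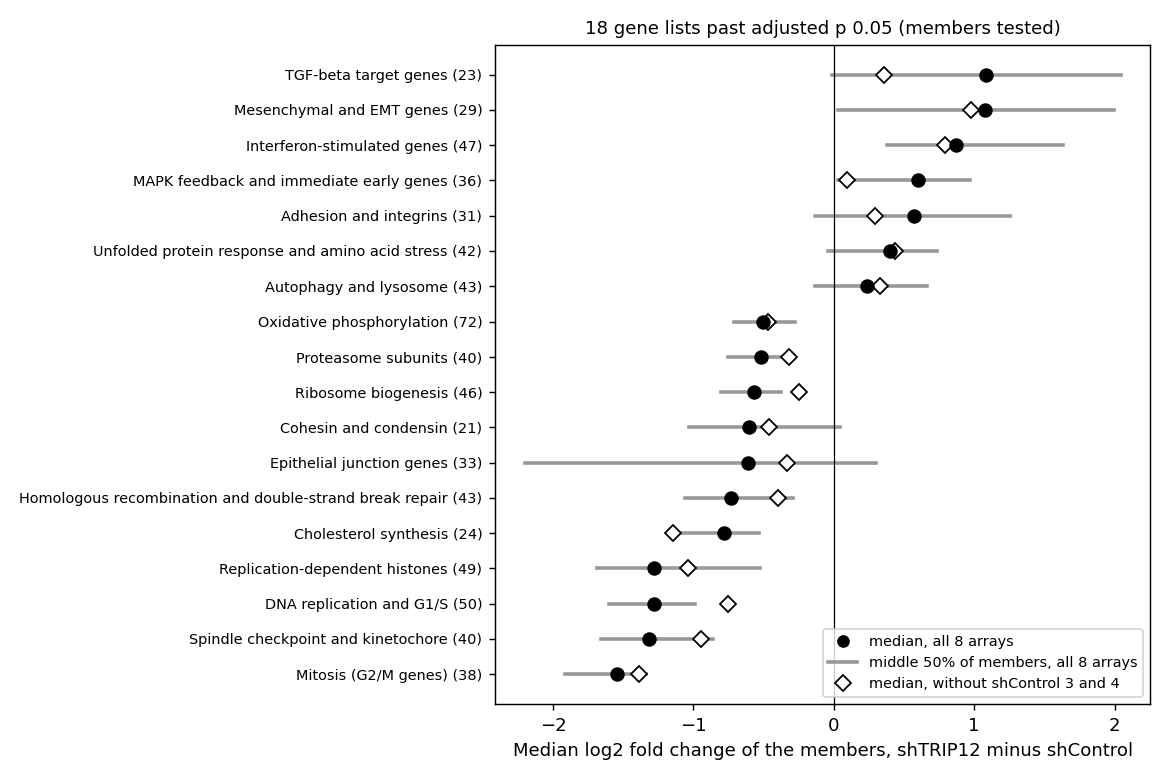
Median log2 fold change (shTRIP12 minus shControl) of the 18 gene lists past an adjusted p of 0.05 in camera with the preset correlation; filled circles are all 8 arrays, open diamonds leave out shControl 3 and 4, and grey lines span the middle 50% of members. Mitosis genes had the lowest median (-1.54), and all 18 medians kept their direction without shControl 3 and 4.

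The remaining 18 lists did not pass. Targets of p53, the tumour suppressor, had a median of -0.08 (adjusted p = 0.972), with FAS at -1.96 and ZMAT3 at 1.21, each past the threshold adjusted over the list alone. Leaving out shControl 3 and 4, 1 p53 target fell and 0 rose past that threshold. Substrates and partners of TRIP12 had a median of -0.12 (adjusted p = 0.599), with FBXW7 at 0.54 and SMARCB1 at -0.64 (-0.34 without shControl 3 and 4), HECT ligases 0.13 (adjusted p = 0.311), and SWI/SNF and chromatin remodelling genes -0.08 (adjusted p = 0.348). NF-kappaB and cytokine genes had a median of 0.44 (adjusted p = 0.0898) but 1.40 without shControl 3 and 4, where the list passed (adjusted p = 8.45e-06, adjusted p = 0.646 with an estimated correlation), with TNFSF10 at 3.71 and CSF1 at 1.88. NRF2 antioxidant genes had a median of 0.28 (adjusted p = 0.221) and 0.32 without those arrays (adjusted p = 0.0351, adjusted p = 0.564 with an estimated correlation). The NF-kappaB list also passed without shControl 3 (median 0.75, adjusted p = 0.0117), shControl 4 (0.77, adjusted p = 0.0184), shTRIP12 1 (0.52, adjusted p = 0.0275) or shTRIP12 3 (0.50, adjusted p = 0.0287), and the NRF2 list without shControl 4 (0.46, adjusted p = 0.0255). The extracellular matrix list, with a median of 0.36 (adjusted p = 0.0638), passed without shControl 2 (0.25, adjusted p = 0.0461), shTRIP12 3 (0.50, adjusted p = 0.0310) or shTRIP12 4 (0.41, adjusted p = 0.0322). Within slide 1 the NF-kappaB (0.94, adjusted p = 0.000316), NRF2 (0.94, adjusted p = 0.00714) and extracellular matrix lists (0.40, adjusted p = 0.00852) all passed, while within slide 2 their medians were -0.034, -0.16 and -0.017. With other normalizations or filters the extracellular matrix list passed in 5 settings (adjusted p = 0.0227 to 0.0483), the NF-kappaB list in 4 (0.0255 to 0.0415) and the NRF2 list in 1 (0.0483). Notch and Wnt targets had a median of 0.55 (adjusted p = 0.199), -0.31 without shControl 3 and 4, and -0.18 and 1.32 within the slides, and passed with array weights (0.92, adjusted p = 0.0447). Medians were -0.08 for hypoxia and glycolysis genes (adjusted p = 0.599) and -0.09 for cytosolic ribosomal protein genes (adjusted p = 0.570). YAP/TEAD targets (-0.09, adjusted p = 0.972) and heat shock genes (-0.12, adjusted p = 0.984) had negative medians while camera gave the positive direction. The p53, heat shock, hypoxia, ductal and endocrine lists had negative medians and positive means. Among markers of other cell types, medians were -0.15 for acinar (adjusted p = 0.704), -0.26 for ductal (adjusted p = 0.774), -0.22 for endocrine (adjusted p = 0.570), -0.22 for fibroblast (adjusted p = 0.556), -0.26 for immune (adjusted p = 0.204) and -0.47 for endothelial genes (adjusted p = 0.659).

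Fold changes were also placed along the genome, since neighbouring genes move together where copy number differs. Camera called 0 of the 23 chromosomes tested (3 at an unadjusted p under 0.05), with a lowest adjusted p of 0.214. Without shControl 3 and 4 it called 2 of them, chromosome 6 with a median of 0.21 and chromosome 10 with a median of -0.11 (adjusted p = 0.0189 each). The running median over 41 neighbouring genes had an SD of 0.233, which is 2.20 times the mean of 1000 random gene orders, and no random order reached it (highest 0.115, permutation p = 0.000999, the smallest that 1000 orders can give). The ratio was 1.73 without shControl 3 and 4, 1.58 within slide 1 and 2.68 within slide 2. Single pairs among the arrays other than shControl 3 and 4 gave ratios of 1.52 to 2.26. For shControl 1 against shControl 2 it was 2.13. The random gene orders therefore cannot tell a difference between the groups from one between replicates.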

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

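The tests of slide or scan batch and of a mixture with other cells, the values without shControl 3 and 4, and the comparison of single array pairs were chosen after the results had been seen, and the other tests were written down before their values were computed. The rule of a 4-fold difference within each slide was also chosen after gene values had been seen.

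The divergence of shControl 3 and 4 moved 1142 genes, VIM and CDKN2A among them, by at least 8-fold against shControl 1 and 2. A slide or scan batch is argued against, because the shTRIP12 arrays of the same slides carried 0.0237 of that difference (slope through 0), and so is scaling, because at least 99.5% of 644 bright genes stayed 4-fold apart under every other normalization. PANC-1 cells mixed with a share of other cells is argued against as well, since 31 of 3641 genes bright on the other 6 arrays lay under 1% of their level there. RNA of a different cell line remains open: neighbouring genes moved together 2.54 times as strongly as in random gene orders, against 1.52 to 2.26 for the 15 pairs among the other 6 arrays, and single pairs of shControl 3 or 4 against 1 or 2 gave 2.30 to 2.61. No other profile was available to test whose RNA these arrays carried. For VIM and IL6 the difference between the groups came from these arrays. VIM had means of 8.27 on shControl 1 and 2, 8.24 in shTRIP12 and -1.65 on shControl 3 and 4. IL6 had means of -5.01, -4.77 and 5.72 in the same order. Genes such as EPCAM (2.20, 0.94 and 6.58) could differ between the groups in part for reasons other than TRIP12.

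Cell cycle genes, 176 genes from the mitosis, spindle checkpoint, DNA replication and histone lists, had a median log2 fold change of -1.37, with 92.6% of them lower in shTRIP12. The divergent arrays alone are argued against, since without shControl 3 and 4 the median was -0.9998 with 89.2% lower. That fit leaves slide 2 without controls, but within slide 1, which lacks these arrays, the median was -1.52. A single array is argued against as well, since the median lay between -1.72 and -1.13 with any 1 array left out. Scaling is argued against too, since the median relative to all genes was -1.11 or lower under the 4 other normalizations that do more than shift each array. Of 35 splits of the 8 arrays into 4 and 4, 1 had a median as large, the real grouping with 1.372 against a highest other value of 1.368 for the split that placed shTRIP12 3 with shControl 1, 3 and 4; the 15 splits that keep shControl 3 and 4 together are too few for a share under 0.05. A lower share of dividing cells at harvest, a direct effect of TRIP12 loss on genes such as AURKA, RRM2 and E2F1, and the array column, which is the same for a whole group, all stay open.

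Interferon-stimulated genes such as GBP2, TRIM22 and SAMD9L were higher in shTRIP12 with a median of 0.87. The divergent arrays alone are argued against, since without shControl 3 and 4 the median was 0.79 with 85.1% of members higher. Of 35 splits 1 had a median as large, the real grouping with 0.87 against a highest other value of 0.72; these splits take no account of slide, and the 18 within slides are too few for a share under 0.05. A response to the hairpin RNA itself, an effect of TRIP12 loss and the array column stay open.

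For the 18 genes past the adjusted p, 1 of 35 splits gave a count as large, with 18 against a highest other count of 2, and the same held for the count with a log2 fold change of at least 1 (1 of 35, 18 against 2). All splits that part shControl 3 and 4 gave 0 genes, so only the 15 that keep them together compete, and these are too few for a share under 0.05. For gene lists, 3 of 35 splits gave as many calls, 18 against a highest other count of 18, so chance is not excluded for the number of lists. Every other split called lists too, from 2 to 18 of 36, and the split by slide called 13. A list call with the preset correlation therefore does not by itself set the real grouping apart, however low its adjusted p. For chromosomes the real count was 0, which 35 of 35 splits reach whatever the data (highest other count 6), so the splits decide nothing there. For neighbouring genes, 2 of 35 splits gave an SD as large, 0.233 against a highest other value of 0.238, and chance is not excluded. With 2 and 2 arrays within each slide, 1 of 18 splits had as many genes at least 4-fold apart the same way, 117 against a highest other count of 52, and 18 splits are too few to exclude chance.

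A single array far from the other 3 of its group was found in 14 of 262 groups of 4 values, where 13.1 are due by chance at 1 in 20. MGAT4B was 4.58 on shTRIP12 3 (4.91 to 4.95 on the others), DSN1 -0.60 on shTRIP12 4 (0.24 to 0.36), RFC4 3.29 on shTRIP12 3 (2.55 to 2.56), BLM 1.59 on shControl 3 (0.91 to 1.00), TNC -6.63 on shControl 1 (-3.92 to -3.37), WNT5A -4.67 on shTRIP12 3 (-2.03 to -1.69), EBP 5.32 on shControl 4 (5.99 to 6.09) and ATP5F1C 1.94 on shControl 2 (2.75 to 2.89). List means that stood apart were 3.13 for mitosis on shControl 3 (2.37 to 2.39 on the others), 1.21 for TRIP12 substrates on shTRIP12 1 (1.46 to 1.48), 0.70 for interferon-stimulated genes on shTRIP12 3 (1.24 to 1.32), 0.36 for Notch and Wnt targets on shTRIP12 2 (-0.11 to -0.03) and -2.40 for fibroblast markers on shControl 2 (-2.83 to -2.80). The mean correlation to its own group was 0.898 for shControl 1 (0.909 to 0.910 for the other shControl arrays). The difference between groups itself differed between slides in 1192 genes past an adjusted p of 0.05 in limma. The divergence of shControl 3 and 4 enters this count. From slide 1 to slide 2, 871 genes were at least 8-fold lower and 271 higher in shControl, against 68 and 69 in shTRIP12. The retained-intron probe of TRIP12 was higher by 1.30 log2 units in shTRIP12 while the mRNA probe was lower.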

How the results depend on the processing

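The fits without shControl 3 and 4 and within each slide were chosen after the results had been seen, while 27 other settings were planned, and where values differ the cause was not tested. TRIP12 had a log2 fold change of -2.31 with normexp background, -2.41 with slide as a block, -2.05 with array weights, -1.81 within slide 2, -0.55 as mean of its probes, 1.30 at its second brightest probe and -2.61 to -2.24 with 1 array left out. Over 23 settings its adjusted p lay between 0.0152 and 0.307 and passed in 5. The count of genes past the adjusted p, with the count that also had a log2 fold change of at least 1, was 47 and 47 with normexp, 11 and 11 with quantile normalization, 11 and 11 with median scaling, 1064 and 928 with slide as a block, 3940 and 3324 with array weights, 2 and 2 with replicate number as a block, and 3632 and 3629 within slide 2. It was 0 and 0 without a filter on dim probes (4807 at an unadjusted p under 0.05 in limma), for probes above background on all 8 arrays (3610), without shControl 3 and 4 (2827) and within slide 1 (3169). With 1 array left out it ranged from 0 to 277 for both counts, and testing every probe gave 9. Of the 18 genes, 11 or 12 stayed past the threshold under the other normalizations, all 18 with slide as a block or array weights, and 0 with replicate number as a block. Deviations of same-numbered arrays from their group means correlated at 0.163, -0.109, 0.008 and 0.189. These values cannot tell whether replicate numbers pair the samples. The shControl deviations hold the divergence of shControl 3 and 4, which the shTRIP12 arrays lack. Without shControl 3 and 4, 2 chromosomes passed against 0. Of the 36 lists, 0 passed with an estimated correlation, 0 with fry and 7 at second brightest probes (16 to 19 with 1 array left out). Medians of 15 lists changed sign in at least 1 setting. p53 targets had 0.023 as mean of probes, 0.16 at second probes, 0.29 and 0.11 within slides 1 and 2, and -0.17 to 0.12 with 1 array left out. YAP/TEAD targets had 0.027 with quantile normalization of processed signals, 0.034 with that of median signals, 0.029 in the deposited values, 0.014 without shControl 3 and 4 and -0.22 to 0.20 with 1 array left out. Heat shock genes had 0.042, 0.038, 0.035, 0.037 and -0.22 to 0.15 in the same order. Without shControl 3 and 4, cytosolic ribosomal proteins had 0.14, Notch and Wnt targets -0.31 and endothelial markers 0.24. Within slide 1, MAPK genes had -0.14, cytosolic ribosomal proteins 0.015, Notch and Wnt targets -0.18, acinar markers 0.055, endothelial markers 0.52 and ATF5 -0.028. Within slide 2, extracellular matrix genes had -0.017, NF-kappaB genes -0.034 and NRF2 genes -0.16. With 1 array left out, ribosomal proteins ranged from -0.20 to 0.031, hypoxia genes from -0.29 to 0.060 and ductal markers from -0.31 to 0.0085. At second probes the unfolded protein response had -0.10, hypoxia genes 0.32, CDCA5 0.067 and H2BC21 0.45, where another probe of the same gene is read, and fibroblast markers had 0.16 as mean of probes. With array weights NF-kappaB genes had -0.31 and NRF2 genes -0.070. SYCN had -0.084 with normexp and -0.019 in the deposited values.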

Other observations

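The rule used here, a difference of at least 4-fold in the same direction within each slide, was chosen after the gene values had been seen, and so were the genes named from it. No list was fixed or tested for them. It was met by 117 of 18585 genes well above background on all 8 arrays, 59 higher and 58 lower in shTRIP12, of which 2, CLPSL2 and MNX1, passed the adjusted p over all genes. Among the higher genes, the prohormone-processing carboxypeptidase gene CPE differed by 4.24 log2 units (4.86 without shControl 3 and 4), the intermediate filament gene NES by 4.08 (2.51) and NDRG4 by 3.95 (2.97). The death ligand gene TNFSF10 differed by 3.71 (4.02), GBP4, an interferon-induced relative of GBP2, by 3.40 (3.19), the lysosome-associated gene GPNMB by 3.39 (3.12) and the claudin gene CLDN4 by 2.82 (2.05).

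Among the lower genes, the zinc finger repressor gene ZNF503 differed by -4.58 (-4.71 without shControl 3 and 4), ERBB3, a receptor of the epidermal growth factor family, by -3.66 (-2.49), the protease inhibitor gene SPINT1 by -3.41 (-3.54), CDH1 by -3.39 (-2.57) and the transcription factor gene KLF5 by -3.12 (-1.80). The centromere protein gene CENPU differed by -2.84 (-1.86), the kinase gene AURKB by -2.31 (-1.66), the cyclin gene CCNB2 by -2.16 (-1.55) and GTSE1 by -2.13 (-1.57). The histone genes H3C15 (-2.93), H3C12 (-2.55), H3C7 (-2.37) and H3C10 (-2.10) stood at -1.83, -1.36, -1.28 and -1.19 without shControl 3 and 4.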
